A study of Physcomitrium patens with 10 samples.

How the data were processed

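The samples were wild-type plants of the moss Physcomitrium patens, either mock-treated or inoculated with the necrotrophic fungus Botrytis cinerea and collected 0.5, 1, 2 or 3 days post inoculation (dpi). Polyadenylated RNA was sequenced. Each of the 5 groups had 2 libraries, 10 in all. A code in the labels places 1 library of every group in each of 2 library series, called series 1 and series 2 here, and replicate 1 of each group belongs to series 1. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

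The authors deposited 1 table per library with a gene ID, a length, a read count and an FPKM value, per the file headers. Counts were whole numbers and were taken as the authors' raw counts per gene. FPKM values were the authors' values scaled for gene length and depth, per the file headers, and were used only in an alternative test. TopHat2 and Bowtie2 are named in the submitters' processing notes, without versions. The genome build, annotation and counting program are not given in the sources used here. Total counts ranged from 15884015 to 24596404 per library.

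The deposited tables of series 2 labelled 0.5 dpi and 1 dpi were identical, with equal counts for all 21011 IDs. Which label the table belongs to could not be worked out. The plan fixed before the data were examined was to fit all 10 libraries. Because of the identical tables the fit used 8 libraries and left that table out of both groups, so that 0.5 and 1 dpi had 1 library each, assumed to vary like the other groups. This departure was decided before any count of called genes was seen. The planned fit, with the identical table under both labels, was kept as an alternative. The 3 added fits, chosen after seeing the tables, used the identical table under 0.5 dpi alone, under 1 dpi alone, or once in an early group that joined 0.5 and 1 dpi. The early group had 3 libraries, and that fit had 9.

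The tables of the 2 series listed different gene models, with 35542 rows in series 1 and 21011 in series 2. The analysis used the 14998 IDs found in both, of which 738 were gene symbols. Another 611 shared IDs of newly assembled genes were left out, because 0 of them had the same length in both. The IDs used held 81.2% to 82.7% of each library's counts. Their lengths differed between the series for 73.7% of IDs, a difference that the series term of the model absorbs where it acts alike on all groups. In series 2, 4312 rows carried several IDs joined into 1 name and were left out. In an added alternative they were given to the last ID of the name, whose length lay within 10% of the series 1 length in 75.2% of cases, against 4.6% for the first ID. The reference gene table matched 2 IDs, so names come from the symbols in the deposited tables.

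Genes were filtered with filterByExpr and scaled with TMM in edgeR 4.0.16 (R 4.3.3), and tested with edgeR's robust quasi-likelihood test with series as a block. P-values were adjusted by the Benjamini-Hochberg method at 0.05, and 14350 genes were tested. The fit had 2 residual degrees of freedom, and the fit with the early group had 4. If no gene differed and the p-values were exact, a share of about 0.05 of the genes would have an unadjusted p under 0.05. Between times, 54 to 108 of 14350 genes did, far below that share, so it is only a rough guide for this fit. Samples of the same series deviated together from their group means, with correlations across genes of 0.24 to 0.74 between mock, 2 dpi and 3 dpi. The pairing comes from the series code in the labels. Alternatives were the fit without the block, DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 1), other size factors and filters, a fold minimum of 2, the 2 groups alone, and each library left out in turn.

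The planned gene lists need product descriptions, which are not in the sources used here, so they were not filled. In their place 26 lists of gene symbols were written after the tables and a few of their counts had been seen and before any test between groups was run. They were tested with camera at a preset correlation of 0.01, adjusted over the lists and the 4 times together, or over the lists alone for the early group, and again with an estimated correlation.

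The planned rule for named genes required a called gene with a description and named none. A second rule was therefore added after the counts of called genes, the correlations between series and the values of some symbols present in 1 series had been seen. It takes genes with a symbol, a mean of at least 5 CPM (counts scaled to a common library size) in the higher group, and a log2 change of at least 1 in size and of the same sign from the mock library of the same series in every library of the comparison. At most 12 genes per direction were taken. Genes without a symbol were held to the same limits and counted, and only examples of them are named. Log2 changes per library used a prior count of 2. Other genes named as members of a list were chosen after their values were seen.

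Each test was checked on simulated counts for 2 dpi against mock, with 200 genes changed. The changed genes were drawn from genes with a mean of at least 100 counts, so recovery at lower counts was not checked. The recovered shares need not hold for the real genes. In the real edgeR fit at 2 dpi PHYPADRAFT_178985 had a log2 fold change of 4.99 ± 0.42 (SE) and was not called (adjusted p = 0.51). With the spread of these libraries, edgeR recovered 58 of 100 genes changed 4-fold and 96 of 100 changed 16-fold, and called 17 unchanged genes among 14279 genes. DESeq2 recovered 83 and 98 of these and called 69 unchanged genes. The limma test recovered 59 and 96 and called 19 unchanged genes among 13698 genes. With a low spread, edgeR recovered 100 and 100 and called 14 unchanged genes, DESeq2 recovered 99 and 100 and called 3, and limma recovered 99 and 100 and called 11.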

Results

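Gene expression was measured by RNA sequencing in the moss Physcomitrium patens after mock treatment and at 0.5, 1, 2 and 3 dpi with Botrytis cinerea, a fungus that kills and feeds on plant tissue. Each group had 2 libraries, 1 in each of 2 library series. Total counts ranged from 15884015 to 24596404 per library, and the lowest total was that of the series 1 library at 3 dpi. The tables of series 2 labelled 0.5 and 1 dpi were identical and are treated as 1 library of an early group. Changes are given as log2 differences from the mock library of the same series. The collection time of the mock libraries is not given, so these changes can include a difference in collection time.

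In series 1 the number of genes at least 2-fold from mock was 799 at 0.5 dpi, 1061 at 1 dpi, 1490 at 2 dpi and 3356 at 3 dpi, of 14350 genes. In series 2 it was 2393 for the early library, 2414 at 2 dpi and 2195 at 3 dpi. The 3 inoculated libraries of series 2 differed from each other by at least 2-fold in 437 to 554 genes. These counts compare single libraries and have no replicate check. Changes in series 1, here and below, take the mock and 3 dpi labels as given. An exchange of these labels was not excluded and is taken up under the other observations.

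**Figure D1:**
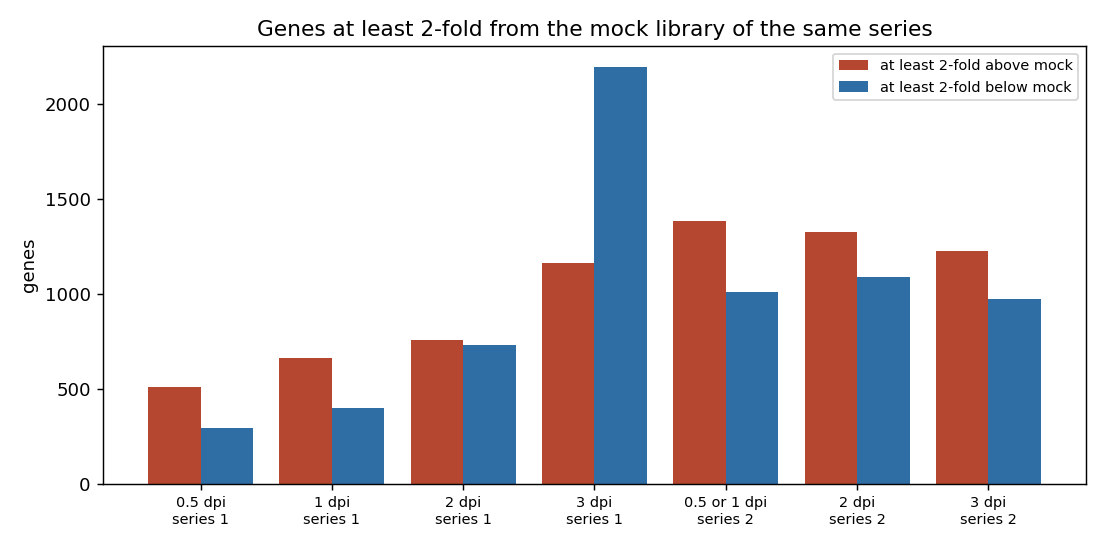
Number of genes (vertical axis) at least 2-fold above or below the mock library of the same series, for each inoculated library (horizontal axis). In series 1 the bars reach 1163 genes above and 2193 below mock at 3 dpi, and in series 2 the early library has 1385 above and 1008 below.

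The first comparison asked which transcripts differ from mock within the first day. In means and counts over the 3 early libraries, the 0.5 and 1 dpi changes of series 1 share 1 mock library. The 3 values are therefore not independent. The gene cslD8, a member of the cellulose synthase-like D family, had a mean log2 change of 1.93 ± 0.19 (SD, n = 3) over the 3 early libraries, from 6.7 to 27.9 CPM at 0.5 dpi in series 1. Ppena1, which encodes a sodium-pumping ATPase, was at 1.66 ± 0.52. The transcription factor gene WRKY27 was at 1.59 ± 0.84, and MSCL14, a mechanosensitive channel-like gene, went from 2.6 to 5.4 CPM at 0.5 dpi in series 1 and from 2.7 to 6.0 in series 2. Below mock were FTR2 at -2.53 ± 0.51 and FTR1 at -1.25 ± 0.18, and FTR1 went from 2465 to 1178.2 CPM at 0.5 dpi in series 1. In the edgeR fit FTR2 was at -2.41, and at -1.37 without mock replicate 1, while WRKY27 was at 1.69, and at 2.63 without mock replicate 1 and 1.10 without mock replicate 2. No other gene with a symbol met the rule for named genes. Among genes without a symbol, 81 above and 35 below mock met the same limits. Examples were PHYPADRAFT_124122 at 4.79 ± 0.85 and PHYPADRAFT_184189 at -2.95 ± 0.40.

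DESeq2 called each of the genes named above for the early group, with adjusted p-values from 3.1e-13 for cslD8 to 0.039 for FTR1. None of them passed edgeR's test. It called 0 genes at 0.5 dpi, 0 at 1 dpi and 0 for the early group, with 263, 390 and 1571 genes at an unadjusted p under 0.05. DESeq2 called 11, 13 and 443 genes, and limma on FPKM called 0, 0 and 0. Without mock replicate 1, edgeR called 51 genes at 0.5 dpi and 607 for the early group; those fits kept 1 mock library, from series 2, with 1 and 3 residual degrees of freedom, and assumed that it varies like the other groups.

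The 2 lists of symbols that rose in the early group did so by camera with the preset correlation. The cellulose synthase and related list had an adjusted p = 0.0083, and 0.015 at 0.5 dpi and 0.017 at 1 dpi; with an estimated correlation the adjusted p = 0.76 in the early group and 0.93 at both times. With edgeR 0 of its 17 members were called in the early group, or 1 when adjusted over the list alone, and DESeq2 called 1, cslD8, with an adjusted p of 3.1e-13. Of the members 4 were above mock in all 3 early libraries. Its median log2 change was 0.20 in series 1 and 0.72 in series 2. The series 2 value included cslA1, at 1.44 in series 2 and -0.16 and -0.15 in series 1. The calcium-dependent protein kinase list, kinases activated by calcium, had an adjusted p = 0.043, and adjusted p = 0.76 with an estimated correlation. It was called at 0.5 dpi (adjusted p = 0.017, and 0.93 with an estimated correlation) and not at 1 dpi (adjusted p = 0.20). With edgeR 0 of its 10 members were called, or 1 when adjusted over the list alone, and DESeq2 called 1, cpk9. Of the members 7 were above mock in all 3 libraries, among them cpk1 at 0.48 ± 0.02 (SD, n = 3) and cpk18 at 0.48 ± 0.26.

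At 1 dpi the list of early light-induced proteins and PSBS, chloroplast proteins of light protection, rose with an adjusted p = 0.017, and adjusted p = 0.93 with an estimated correlation. That test used 1 library at 1 dpi and 8 members. The list was not called at 0.5 dpi (adjusted p = 0.14) or in the early group (adjusted p = 0.48), where 6 members were tested and the 0.5 dpi library and the library of series 2 were added; which of these ended the call was not tested. ELIP13 was at 2.95 in that library and at -0.19 in the early library of series 2, and ELIP5 at 2.10 and 1.28. PSBS was at -0.87 and 0.69. The list of MADS-box and LEAFY genes, chosen as markers of reproductive tissue, rose at 0.5 dpi with an adjusted p = 0.035, and adjusted p = 0.93 with an estimated correlation. That test also used 1 library, and the list was not called at 1 dpi (adjusted p = 0.20) or in the early group (adjusted p = 0.077). Of its 14 members, 6 were above and 1 below mock in all 3 early libraries. At 3 dpi 8 were above and 0 below mock in both series. PPTIM7, one of its members, was called lower by DESeq2 in the early group. It was at -4.96 in the early library of series 2 and at 4.64 at 3 dpi in series 1.

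At 2 dpi, 8 genes with symbols were above mock by the rule in both series. NRT2%3B2, a nitrate transporter gene, went from 0.3 to 15.0 CPM in series 2 and was near the floor in series 1, at 0 CPM in mock and 0.4 at 2 dpi. WRKY27 had a mean log2 change of 2.22 ± 0.65 (SD, n = 2), cslD8 at 1.64 ± 0.09 and Ppena1 at 1.71 ± 0.65. The homeodomain-leucine zipper gene Pphb7 was at 1.63 ± 0.24. The hexokinase gene hxk11 was at 1.27 ± 0.08, MSCL14 at 1.14 ± 0.14 and CKI2a at 1.04. FTR1 and FTR2 were below mock, at -1.54 ± 0.24 and -2.06 ± 1.14. The value of FTR2 depended on the mock library: in the edgeR fit it was -2.23, and -0.97 without mock replicate 1 and -3.09 without mock replicate 2. Among genes without a symbol, 160 above and 98 below mock met the same limits, with PHYPADRAFT_178985 at 4.93 ± 0.06.

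For 2 dpi edgeR called 0 genes, with 704 at an unadjusted p under 0.05. In this fit, which leaves out the identical table, that is no more than the share of 0.05 that would arise if no gene differed. DESeq2 called 117 genes, 76 higher and 41 lower than mock, and limma on FPKM called 0. Among the DESeq2 genes were cslD8 with a DESeq2 adjusted p of 0.0064 and Pphb7 with 0.0052. The named genes hxk11, MSCL14, CKI2a and FTR1 were not called by DESeq2 at 2 dpi. The planned fit of all 10 libraries as labelled called 3 genes with edgeR, none with a symbol. That fit counts the identical table as 2 libraries, which understates the spread, so its calls alone cannot be relied on. With the table entered once, in the early group, edgeR called 2 genes, and both were among those 3. They were PHYPADRAFT_144609 at 4.06 ± 0.29 (SE) and PHYPADRAFT_168872 at 2.74 ± 0.15. Without mock replicate 1, again with 1 residual degree of freedom, edgeR called 115 genes.

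At 3 dpi, Pphb7 was again above mock in both series, at 1.74 ± 0.12 (SD, n = 2). NRT2%3B2 was near the floor in series 1, so that its change there depended on the prior count: it was at 0 CPM in mock and 0.2 at 3 dpi; in series 2 it went from 0.3 to 12.8 CPM. MSCL4 was at 1.98 ± 1.03 and the ABC transporter gene ppabcc7 at 1.04 ± 0.06. Below mock were Per1 at -2.40 ± 0.35, the phytochrome gene PHY5a at -1.32 ± 0.09 and the hexokinase gene hxk2 at -1.32 ± 0.33. FTR1 was at -1.73 ± 0.89 and FTR2 at -2.36 ± 1.87. In the edgeR fit FTR2 was at -2.42, and at -1.28 without mock replicate 1 and -1.49 without 3 dpi replicate 1. Without 3 dpi replicate 1, MSCL4 went from 2.08 to 1.33 and Per1 from -2.41 to -1.59. Among genes without a symbol, 92 above and 177 below mock met the same limits, with PHYPADRAFT_143870 at -5.04 in both series.

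For 3 dpi edgeR called 0 genes, with 873 at an unadjusted p under 0.05. DESeq2 called 175, of which 65 were higher and 110 lower than mock, and limma on FPKM called 0. Among the DESeq2 genes were Pphb7 with a DESeq2 adjusted p of 0.0014, NRT2%3B2 with 0.00016 and MSCL4 with 0.02. FTR1 with 0.016 and FTR2 with 0.018 were also among them. Per1, PHY5a, hxk2 and ppabcc7 were not called by DESeq2. The planned fit of all 10 libraries called 1 gene with edgeR, but it counts the identical table as 2 libraries. With the table entered once, in the early group, edgeR called 0 genes at 3 dpi.

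**Figure D2:**
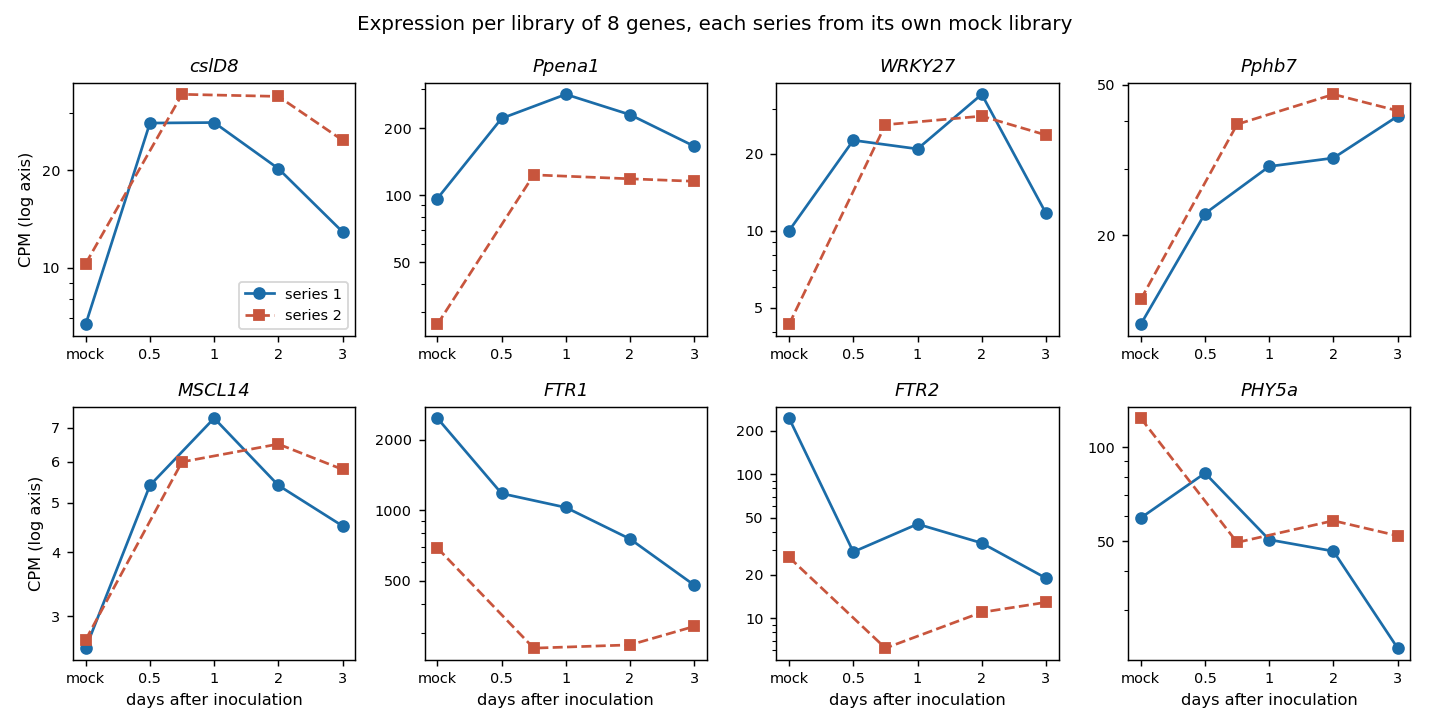
CPM on a log axis (vertical) in each library, from mock to 3 dpi (horizontal), for 8 named genes, with series 1 as circles and series 2 as squares; the identical early table of series 2 is drawn once, midway between 0.5 and 1 dpi. For Pphb7 both series lie above their mock libraries throughout, and for FTR1 both lie below.

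The WRKY transcription factors and lipoxygenases, families linked to plant defence and to oxylipin synthesis, gave 0 called genes with edgeR at 2 and 3 dpi, and camera gave no call. At these times DESeq2 called 1 of them, WRKY27 at 2 dpi, with an adjusted p of 0.049. In the early group DESeq2 called WRKY27, WRKY30 and PpLOX7. There edgeR called 0 genes of either family, or 1 in each when adjusted over the list alone. Of 19 WRKY genes, 7 were above mock in both series at 2 dpi and 4 below. WRKY29 was at 1.89 in series 1 and -0.82 in series 2 at 2 dpi, and WRKY6 at 1.67 and -0.79 at 3 dpi. Of the 7 lipoxygenase genes tested, PpLOX7 alone was above mock in both series at 2 dpi, at 1.14 ± 0.68 (SD, n = 2). At 3 dpi 4 of the 7 were below mock in both series and 1 above, while PpLOX11 was at 2.95 in series 1 and -1.55 in series 2. The other symbol lists had 0 genes called by edgeR at 2 and 3 dpi, while the cellulose synthase list had 1 at 2 dpi when adjusted over the list alone. DESeq2 called cslD8 and the MADS-box gene PPTIM3 at 2 dpi and MSCL4 at 3 dpi among their members. Camera called 0 of the 26 lists at either time.

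The changes in the 2 series were compared across genes, which are not independent replicates. Pearson's r between the series was 0.25 at 0.5 dpi, 0.22 at 1 dpi, 0.13 at 2 dpi and -0.11 at 3 dpi. The values at 0.5 and 1 dpi share the early library of series 2, whose time is not known, and both mock libraries. They are therefore not separate comparisons. At 2 dpi 266 genes were at least 2-fold above mock in both series, against 70.0 for independent lists, and 149 below in both, against 55.6. Opposite changes also exceeded independent lists, with 118 above in series 1 and below in series 2, against 57.5, and 131 the other way, against 67.6. At 3 dpi 152 were above in both, against 99.3, and 233 below in both, against 148.2, while 250 were above in series 1 and below in series 2, against 78.6, and 353 the other way, against 187.2.

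Tests between times asked whether expression moved on from one collection to the next. With edgeR 0 genes differed between 0.5 and 1 dpi, 0 between 1 and 2 dpi and 0 between 2 and 3 dpi, with 54, 108 and 89 at an unadjusted p under 0.05. DESeq2 called 0, 4 and 1, and limma called 0 in each. The test of all 4 times together called 0 genes with edgeR, with 321 at an unadjusted p under 0.05, 115 with DESeq2 and 0 with limma. For 2 dpi against the early group edgeR called 0, with 362 at an unadjusted p under 0.05, DESeq2 4 and limma 0. Among the edgeR counts given above, only those for 3 dpi and the early group against mock exceeded a share of 0.05 of the genes tested. Some alternative fits exceeded that share at other times, and others did not. At 2 dpi against mock, 1464 of 14173 genes had an unadjusted p under 0.05 in the fit with the early group. Without the replicate block it was 426 of 14350. With the identical table under its label, it was 879 of 14342 at 0.5 dpi and 1028 of 14342 at 1 dpi.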

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

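The 4 genes WRKY24, WRKY11, PpLOX6 and ELIP12, present under their own name only in the tables of series 1, stood above their mock level after inoculation, each in single libraries. WRKY24 was at 4.8 CPM in mock and 55.3 at its highest, and WRKY11 at 13.3 and 84.4. The lipoxygenase gene PpLOX6 went from 385.6 to 904.7 CPM. ELIP12, an early light-induced protein gene, was at 29.6 in mock, 178.4 at 1 dpi and 6.2 at 3 dpi. In series 2 the names of WRKY11, PpLOX6 and ELIP12 occur as the last part of joined names, and those rows did not repeat the higher level throughout. There the log2 changes from mock in the early, 2 dpi and 3 dpi libraries were -1.26, -1.58 and -1.39 for WRKY11. They were -0.29, -0.40 and -0.29 for PpLOX6, and 0.77, -1.72 and 0.26 for ELIP12, which was at 1.4 CPM in mock. WRKY24 was not analysed in series 2.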

How the results depend on the processing

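The fits with the identical table under 1 label, the last-ID matching, the early group, the symbol lists and their alternatives were chosen after seeing the data; the fit of 10 libraries was planned, and its use as an alternative was not. With edgeR, the counts of called genes were 0 without the replicate block, and 0 with DESeq2 size factors, library totals, no filter, the filter at 10 CPM, the last ID of joined names, the identical table under 0.5 or 1 dpi alone, and only the 2 groups compared. A fold minimum of 2 could only give 0, since it was applied to 0 called genes. These zeros cover the comparisons that each setting was run for. The 2 groups alone gave no value for 1 against 0.5 dpi, which left no residual degrees of freedom, and were not run for any time or for 2 dpi against the early group. The identical table under 1 label was not run for the early group. DESeq2 called 11, 13, 117 and 175 genes at 0.5, 1, 2 and 3 dpi, 115 at any time, 4 for 2 against 1 dpi, 1 for 3 against 2 dpi, 443 for the early group and 4 for 2 dpi against it. In simulated counts with the spread of these libraries DESeq2 called 69 unchanged genes against 17 for edgeR, and with a low spread 3 against 14, so part of its excess may be false at the spread of these libraries; for the real genes the cause was not tested. The 10 libraries as labelled gave 3 genes at 2 dpi and 1 at 3 dpi, but that fit counts the identical table as 2 libraries, which understates the spread. With 0.5 and 1 dpi as 1 group, which enters the table once, there were 2 genes at 2 dpi, both among those 3, and 0 at 3 dpi. The cause of these calls was not tested. With each library left out in turn, counts ranged from 0 to 51 at 0.5 dpi, 0 to 115 at 2 dpi, 0 to 89 at 3 dpi and 0 to 607 for the early group. The highest each came without mock replicate 1, where the lone mock library is assumed to vary like the other groups, and without mock replicate 2 there was 1 gene at 2 dpi and 1 at 3 dpi; the cause was not tested.

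The lists called were 3 at 0.5 dpi, 2 at 1 dpi and 2 in the early group. With an estimated correlation they were 0, 0 and 0. Without the replicate block they were 3, 6 and 4. With each library left out they ranged from 1 to 3, 1 to 2 and 1 to 5, and from 0 to 1 at 3 dpi. For the named genes 413 values under the alternatives were on the same side of the threshold and 41 newly past it; the naming rule fixed their direction, which shows nothing about stability. With 1 library left out, 10 of their 37 fitted changes moved by over 1.5 times. Other settings for the unfilled gene lists, and another FPKM pseudocount meant for files without counts, were not run.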

Other observations

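The tests of the exchanged labels, the depth and the top genes were chosen after the patterns had been seen; those of gene models and low counts were written before their results. Among genes recovered from joined names, the oxylipin gene HPL1, a hydroperoxide lyase, was at 1.27 at 1 dpi in series 1 and 0.49 in the early library of series 2, at 0.82 and 0.37 at 2 dpi, and at -0.60 and -0.01 at 3 dpi. The ABC transporter gene ppabcg3 was below mock in all libraries, at -1.86 and -1.83 at 2 dpi and -2.72 and -1.69 at 3 dpi in series 1 and 2. WRKY11 was at 2.04 in series 1 and -1.58 in series 2 at 2 dpi, and at 2.48 and -1.39 at 3 dpi.

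The changes of the 2 series went against each other at 3 dpi. Over all genes r was -0.107. Over the 3340 genes with equal lengths in both kinds of table it was -0.056 (bootstrap interval -0.112 to -0.004), and over 4783 genes with a mean of at least 50 CPM it was -0.171. Equal lengths do not show equal gene models, so the value for equal lengths cannot exclude differing models. The changes of the 2 series still opposed each other at 50 CPM or more, which argues against low counts as the cause. The negative r over all genes had already done so, since noise from low counts draws r toward 0. With equal lengths the changes of the 2 series opposed each other less, so a part played by differing lengths is not excluded. An exchange of the mock and 3 dpi labels in series 1 needs these changes to oppose each other: the 1440 genes at least 2-fold from mock in every inoculated library of series 2, signed by that direction, had medians of 0.28, 0.25, 0.14 and -0.32 at 0.5, 1, 2 and 3 dpi in series 1 (interval over genes at 3 dpi -0.38 to -0.22), a direction that the negative r had already shown, while the 307 genes at least 4-fold from mock had -0.15 (-0.40 to 0.03) at 3 dpi and the 87 at least 8-fold had 0.09 (-0.28 to 0.33), intervals that include 0. Within series 1 the library labelled 3 dpi was nearest to 2 dpi (2000 genes at least 2-fold apart, against 3346 for 1 dpi and 3280 for 0.5 dpi), and the one labelled mock was nearest to 0.5 dpi (799 genes, against 1061 for 1 dpi and 1490 for 2 dpi), an order that follows the labels but does not exclude an exchange. An exchange therefore stays open as a hypothesis, as does an untested difference in how the plants of the 2 series stood at 3 dpi.

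The mock library of series 2 stood apart from its inoculated libraries, which lay close together. Its total count was 1.027 times their mean and its 10 leading genes took 1.049 times their share, which argue against depth and against a few dominant genes. A response that is already complete at the first collection and a mock library that differs for another reason cannot be separated with 1 mock library in that series, and no test of either was run.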
